A study of Homo sapiens with 14 samples.

How the data were processed

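RNA-seq values of 8 libraries were used, 2 each of MCF7, MCF7△ESR1, Hep3B and Hep3B+ER, grouped by their titles. The 6 chromatin immunoprecipitation samples were not analysed here. Each library had 1 deposited table of 26255 gene rows with an expression value. The deposited values are FPKM, that is fragments scaled to transcript length and to mapped fragments, made by the authors: the submitters' processing notes name TopHat2 and Cufflinks, along with Bowtie2 2.1.0 and HOMER 4.2 and the builds hg19 and GRCh37, without saying which was used for which sample type. The annotation and any filter are not given in the sources used here. Although the tables are called counts, their values are not whole numbers and carry no read depth. Low values did not step in whole reads: over 821 low genes at most 14.3% of the ratios between libraries lay within 5% of a single ratio. Depth is therefore unknown, counting error could not be set against the spread between replicates, and whether the 2 Hep3B+ER libraries differed by more than sampling noise could not be tested. No gene above 0 in both libraries of a group had the same value in both.

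The design fixed before the data were examined assumed counts. The test was changed to limma on the log scale because the values are FPKM, and the samples and contrasts were kept as fixed. Gene names were used as deposited; 23614 names are current symbols, 1430 are older symbols or synonyms and 1211 matched neither, in the gene name tables. Dates had replaced 28 gene names, and the 4 rows whose names then occurred more than once were left out. A further 2293 rows of small RNA genes (miRNA, snoRNA, scaRNA and snRNA genes) were left out of the tests, since FPKM of very short genes is unstable and these rows held 36.5% to 48.4% of summed FPKM. Each library was scaled by the median ratio to the geometric mean over the 9771 genes with at least 1 FPKM in all 8 libraries. Log2 scale factors ran from −0.061 to 0.082. Genes with at least 1 FPKM in at least 2 libraries were tested, 14024 in all, as log2(FPKM + 1), with limma 3.58.1 in R 4.3.3 (mean-variance trend, robust). All 8 libraries entered 1 fit with a mean per group and 4 residual degrees of freedom, so that the groups share 1 estimate of the spread, and Benjamini-Hochberg adjusted p under 0.05 made a call. The contrasts were MCF7△ESR1 against MCF7, Hep3B+ER against Hep3B, Hep3B against MCF7, and the difference of both ESR1 effects, that is the fold change of MCF7△ESR1 against MCF7 minus that of Hep3B against Hep3B+ER. The comparisons of Hep3B+ER with MCF7 and of MCF7△ESR1 with Hep3B were computed in the same fit, the last of them added after seeing the data. Levels are printed as deposited FPKM and fold changes from the scaled values, with limma's SE.

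Of 22 gene lists fixed before the data were examined, 21 had measured members, and the mitochondrially encoded genes were in none of the tables. Lists were tested with camera at a preset correlation of 0.01, adjusted over 21 lists per contrast. They were tested again with an estimated correlation, with fry, and without members shared between lists. The estimate was −0.013 for estrogen-induced genes, −0.012 for Wnt targets and −0.006 for hepatocyte transcription factors. All of these lie below the preset, so calls of these lists lost in that setting were not lost to a larger correlation. Named genes followed a rule fixed beforehand: ESR1; the 10 largest and 10 smallest log2 fold changes per contrast among called genes with at least 5 FPKM in the higher group and no overlap between the groups; up to 4 members per list with at least 1 FPKM; and up to 8 genes for each pair of directions of both ESR1 comparisons. Symbols of the forms LOC, LINC, MIR, antisense and clone names, among others, were left out of that rule, while noncoding genes with other names, such as H19, were kept. MTAP and TP53 are named outside it, for their known deletion in MCF7 and in Hep3B.

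On simulated data, made from the libraries' means and spread with 200 changed genes, the fit recovered 47% of 100 genes changed by 1 on the log2 scale and 87% of 100 changed by 2 for MCF7△ESR1 against MCF7, with 4 false calls among 12990 genes. For Hep3B+ER against Hep3B it recovered 44% and 88%, with 2 false calls among 13017 genes. In the data 60.6% and 15.7% of the genes were called in these comparisons, far more than were changed in the simulation. Its recovery and false calls therefore need not hold for the data. Alternatives fixed beforehand were no scaling, no filter, the replicate number as a block, only the 4 libraries of a contrast, and leaving out each library. Alternatives chosen after seeing the data were a pseudocount of 0.1, quantile normalization, a filter of 5 FPKM, keeping small RNA genes, leaving out both libraries labelled MCF7△ESR1, counting the Hep3B+ER libraries as 1, and library weights. The order of genes along chromosomes came from RefSeq genes of a newer assembly, GRCh38.p14, and was used only for which genes neighbour each other. Figures and tests of neighbouring genes were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.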

Results

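RNA was sequenced from 8 human cell line libraries in 4 groups of 2: MCF7, MCF7△ESR1, Hep3B and Hep3B+ER. MCF7 is a breast cancer line that expresses estrogen receptor alpha, the product of ESR1, and Hep3B is a hepatocellular carcinoma line. The series asks how this receptor acts in liver cancer and in breast cancer cells. Group names are given as in the labels, which do not spell out the triangle. The 6 chromatin immunoprecipitation samples of the series, 2 of them input, were not analysed here. Each library had 1 value in FPKM for each of 26255 gene rows. FPKM summed to between 700640 and 935226 per library, and small RNA genes held 36.5% to 48.4% of that sum. Between 17406 and 19732 genes were listed above 0. The number of reads behind a value is unknown, so no counting interval or detection floor is given. The labels do not say whether the 2 libraries of a group came from separate cultures, so each adjusted p measures the spread between these libraries, which may be technical. That spread was unequal. The SD of the log2 ratio between replicates over genes of at least 1 FPKM was 0.456 in MCF7, 0.465 in MCF7△ESR1, 0.483 in Hep3B and 0.138 in Hep3B+ER.

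ESR1 itself followed the labels in each library, although a very low level, as in Hep3B, cannot show which line a library came from. Its level was 39.2 and 45.5 FPKM in MCF7 and 0.0699 and 0.108 FPKM in the libraries labelled MCF7△ESR1, a log2 fold change of −5.31 ± 0.14 (SE, n = 2 per group; adjusted p = 3.93e-07). It was 0.0780 and 0.0208 FPKM in Hep3B and 96.6 and 96.0 FPKM in Hep3B+ER, a log2 fold change of 6.58 ± 0.14 (adjusted p = 1.75e-06). All fold changes are on the scale of log2(FPKM + 1), which understates the change of genes with low values. An exact permutation test of 2 against 2 libraries cannot give a two-sided p below 0.333, so each call rests on limma's spread shared across genes and the 4 residual degrees of freedom of the 8 libraries.

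**Figure D1:**
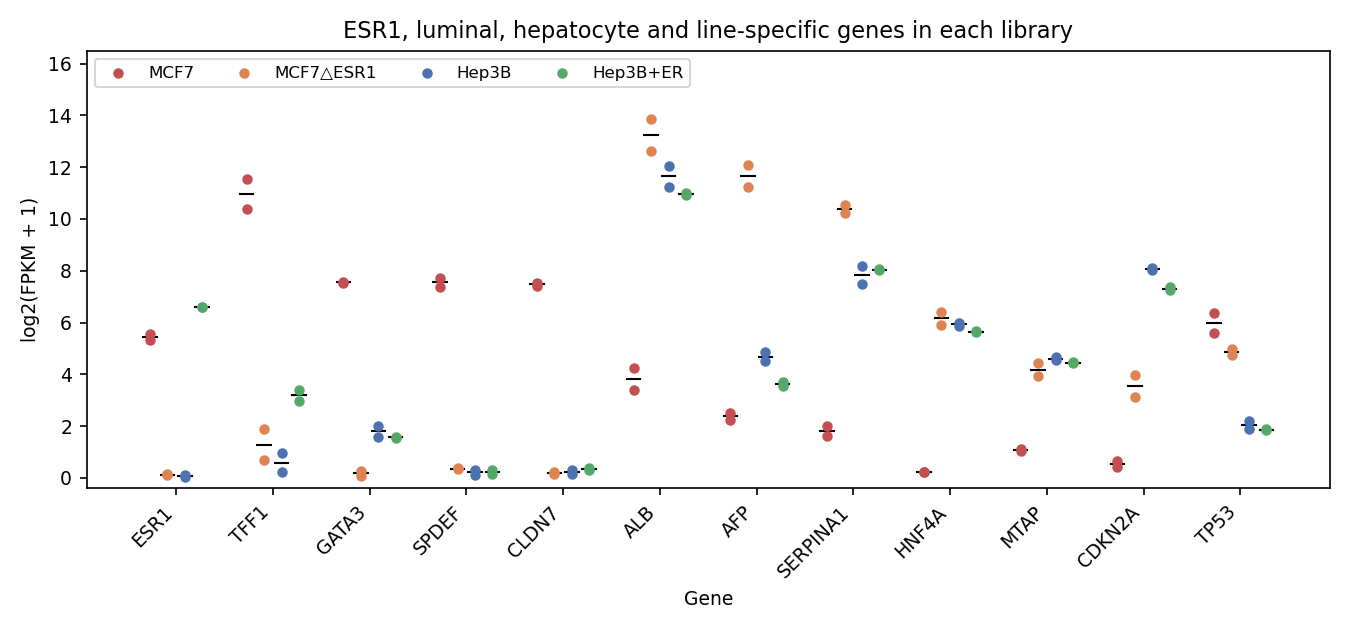
Level of 12 genes as log2(FPKM + 1) on the vertical axis, with 1 point per library, colours for the 4 groups and a black line at each group's mean. ESR1 lies near 0 in the libraries labelled MCF7△ESR1 and in Hep3B, while ALB and AFP in the libraries labelled MCF7△ESR1 lie above every other group, with AFP at 4297 and 2414 FPKM.

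The libraries labelled MCF7△ESR1 were compared with MCF7 as labelled. MTAP, which is known to be deleted in MCF7, was at 14.31 and 20.56 FPKM in them and at 1.02 and 1.17 FPKM in MCF7. The differences below are therefore between the labelled libraries, and ESR1 loss cannot be separated in them from a difference of cell line. TFF1, a classical estrogen-induced secreted peptide, fell from 3014 and 1329 FPKM to 0.593 and 2.67 FPKM (log2 fold change −9.69 ± 0.50, adjusted p = 3.76e-06). GATA3, a luminal transcription factor, fell from 186 and 189 FPKM to 0.208 and 0.0573 FPKM (−7.37 ± 0.19). ALB, which encodes serum albumin, rose from 9.55 and 17.8 FPKM to 14790 and 6343 FPKM (9.44 ± 0.46), and AFP, the fetal counterpart of albumin, rose from 3.75 and 4.67 FPKM to 4297 and 2414 FPKM (9.29 ± 0.27). Among 14024 genes tested, 4380 were higher and 4119 lower (3856 and 4811 with quantile normalization), together 60.6% of the genes. Of these, 2725 and 2154 changed by at least 1 on the log2 scale. With only the 4 libraries of this comparison, which leaves the close Hep3B+ER pair out of the shared spread, 3918 were higher and 3622 lower. The genes with the largest rises also included LYZ, APOH, FGG, A2M, AHSG, APOA2, FN1 and SERPINA1, with log2 fold changes of 8.58 to 9.07. Those with the largest falls also included IFI27, SPTSSB, PREX1, CLDN7, SPDEF, CRABP2, TPD52L1 and S100A14, with log2 fold changes of −9.37 to −6.78. Over the 14024 tested genes the libraries labelled MCF7△ESR1 correlated with the MCF7 libraries at Pearson r between 0.693 and 0.725. Their r with the Hep3B libraries was between 0.812 and 0.847, and that of Hep3B with MCF7 was between 0.734 and 0.738. These correlations run across genes, which are not independent replicates.

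Gene lists fixed before the data were examined changed as follows in the same comparison. Of 54 measured estrogen-induced genes 32 were lower and 8 higher (33 and 8 adjusted over the list alone). Examples are CA12 at −6.38 ± 0.24 and HSPB8 at −6.27 ± 0.40. Camera, limma's competitive set test, gave an adjusted p of 5.10e-05, and adjusted p = 0.0578 with an estimated correlation. Of 25 luminal epithelial markers 21 were lower and 1 higher, the same counts adjusted over the list alone (camera adjusted p = 5.07e-07). With an estimated correlation the adjusted p = 0.0578. ESRP1, a splicing factor of epithelial cells, fell from 79.9 and 70.2 FPKM to 0.282 and 0.0867 FPKM. In the same libraries all 32 measured genes of hepatocyte secreted proteins were higher, also adjusted over the list alone, with a median log2 fold change of 7.40 (camera adjusted p = 1.96e-15). That list had an adjusted p = 0.229 with an estimated correlation. Of 16 hepatocyte transcription factors 14 were higher and 1 lower, also adjusted over the list alone, including HNF4A at 5.95 ± 0.17 and PROX1 at 4.54 ± 0.19 (camera adjusted p = 5.10e-05; adjusted p = 0.0578 with an estimated correlation). Of 25 xenobiotic and bile acid genes 20 were higher and 2 lower, also adjusted over the list alone (camera adjusted p = 1.64e-05; adjusted p = 0.108 with an estimated correlation). AKR1C1, a steroid-reducing enzyme with close paralogs that can share reads, rose from 1.04 and 0.812 FPKM to 324 and 562 FPKM.

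Signalling and receptor genes differed along with these liver genes, whose median log2 fold change was 7.40. Among 15 Wnt target genes 12 were higher and 2 lower, also adjusted over the list alone (camera adjusted p = 8.28e-05; adjusted p = 0.0578 with an estimated correlation). NOTUM, a secreted Wnt inhibitor, rose by 6.52 ± 0.19 and LGR5 by 5.42 ± 0.12. Of 25 p53 target genes 17 were higher and none lower, also adjusted over the list alone, such as GADD45A at 3.76 ± 0.30. Camera gave an adjusted p = 5.61e-05, and adjusted p = 0.431 with an estimated correlation. The list's median was 1.17. In the libraries labelled MCF7△ESR1 23 of these 25 genes were higher in replicate 1, with a median log2 ratio of 0.57. Of 33 steroid and nuclear receptors 17 were higher and 7 lower, also adjusted over the list alone (camera adjusted p = 0.0312; adjusted p = 0.496 with an estimated correlation). NR1H4, the bile acid receptor, rose to 24.7 and 23.4 FPKM. Unfolded protein response genes had 18 of 25 higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.000977; adjusted p = 0.229 with an estimated correlation). Mesenchymal genes had 11 of 20 higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.00941; adjusted p = 0.239 with an estimated correlation). Of 18 leukocyte markers only 7 were measured, and all 7 were higher, also adjusted over the list alone, with LYZ at 1385 and 1906 FPKM. The rest did not reach 1 FPKM in 2 libraries. A member could pass that filter through the libraries labelled MCF7△ESR1 alone, which can shape this share. Camera gave the measured members an adjusted p = 0.000250, and adjusted p = 0.0843 with an estimated correlation. Hypoxia genes had 11 of 25 higher and 3 lower (10 and 2 adjusted over the list alone; camera adjusted p = 0.0292, and adjusted p = 0.567 with an estimated correlation). NF-kB and inflammatory genes had 7 of 20 higher and 1 lower (6 and 1 adjusted over the list alone). Camera gave an adjusted p = 0.0494, and adjusted p = 0.567 with an estimated correlation. The list's median was 0.18 and its mean 1.20. Within MCF7, 18 of these 20 genes were higher in replicate 1, with a median log2 ratio of 0.43.

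In the same libraries, which carried the liver genes above, 18 of 32 G2/M genes were lower and none higher, also adjusted over the list alone (camera adjusted p = 0.000977; adjusted p = 0.567 with an estimated correlation and 0.0518 with fry). KIF23, a kinesin of cytokinesis, had a log2 fold change of −1.72 ± 0.19. Of 30 G1/S genes 14 were lower and 3 higher, also adjusted over the list alone (camera adjusted p = 0.0400; adjusted p = 0.567 with an estimated correlation and 0.0788 with fry). CCNE2, a cyclin, fell by 2.90 ± 0.18 and its paralog CCNE1 rose by 1.86 ± 0.16. Replication-dependent histone genes had 4 of 14 lower (3 adjusted over the list alone), with a median of −1.02. Camera gave an adjusted p = 0.0234, and adjusted p = 0.567 with an estimated correlation. In replicate 1 of the libraries labelled MCF7△ESR1 11 of these 14 genes were higher than in replicate 2 (median log2 ratio 0.70). In MCF7 replicate 1, 1 of 14 was higher (median −0.41). Histone genes have near-identical copies, so their values are uncertain. Of 34 type I interferon genes 27 were lower and 3 higher, also adjusted over the list alone (camera adjusted p = 8.39e-05; adjusted p = 0.567 with an estimated correlation). The 2 MCF7 libraries themselves differed in these genes: 33 of 34 were higher in replicate 1, with a median log2 ratio of 1.72, and IFI27 was at 3879 and 1054 FPKM. Lists without a camera call were the 12 basal epithelial markers (4 higher and 3 lower, adjusted p = 0.519), the 25 cholesterol biosynthesis genes (4 and 4, adjusted p = 0.547), the 18 YAP and TEAD target genes (9 and 2, adjusted p = 0.109) and the 5 fibroblast and endothelial markers (2 and 0, adjusted p = 0.442). Adjusted over the list alone these were 4 and 3, 3 and 3, 9 and 2, and 2 and 0. Fry called the basal markers (0.00577) and the fibroblast and endothelial markers (0.00636), and camera called the YAP and TEAD genes with only the 4 libraries of the comparison (0.0303). The filter of 5 FPKM ended the calls of receptor genes (0.0975) and histone genes (0.117), and a pseudocount of 0.1 that of NF-kB genes (0.0636). Leaving out 1 library ended 5 of the list calls of this comparison. Without MCF7 replicate 2 the adjusted p was 0.0701 for G1/S, 0.287 for NF-kB and 0.148 for histone genes, and without replicate 1 of the libraries labelled MCF7△ESR1 it was 0.195 for G1/S, 0.0634 for NF-kB, 0.0575 for hypoxia and 0.0770 for receptor genes. Without MCF7 replicate 1 it was 0.0604 for hypoxia genes, and without replicate 2 of the libraries labelled MCF7△ESR1 it was 0.166 for histone genes.

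The comparison of Hep3B+ER with Hep3B addresses what differs in the liver line when ESR1 is present. The genes with the largest rises besides ESR1 were SPINK1, a secreted trypsin inhibitor, from 4.38 and 13.2 FPKM to 832 and 780 FPKM (log2 fold change 6.63 ± 0.44, adjusted p = 0.000127), and TUBA1A, an alpha-tubulin with close paralogs that can share reads (5.52 ± 0.44). BEX1, IGFBP2, WFDC2, KRT17 and SMIM24 rose by 4.27 to 5.07. COL4A1 and COL4A2, the neighbouring genes of the main collagen IV chains, rose from below 0.4 FPKM to between 25.8 and 29.9 FPKM. Several abundant Hep3B transcripts fell to almost nothing. H19, an imprinted long noncoding RNA, fell from 2164 and 2091 FPKM to 0.137 and 0.198 FPKM (−10.76 ± 0.27, adjusted p = 3.89e-06). CDKN1C, an imprinted cell cycle inhibitor, was 80.2 and 113 FPKM in Hep3B and was listed at 0 and 0.0345 FPKM in Hep3B+ER, and DLK1, another imprinted gene, fell by 4.81 ± 0.55. TM4SF1 fell by 5.47 ± 0.20 and BGN by 4.02 ± 0.28. KRT7, IFITM2, TMEM59L, WDR76 and ANGPTL3 had log2 fold changes of −3.54 to −2.90.

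Among 14024 genes, 1371 were higher and 828 lower in Hep3B+ER, 15.7% in all, and 632 and 257 of these changed by at least 1 on the log2 scale. Because the 2 Hep3B+ER libraries were so close to each other, they were also counted as 1, an alternative chosen after seeing the data. That left 173 genes higher and 67 lower, all of which were among the genes called before. Without replicate 1 of Hep3B+ER the counts were 178 and 69, and without replicate 2 they were 159 and 72. With the libraries counted as 1, 17 of the 18 large changes that could be tested passed again, and KRT7 did not. The share of higher among the called genes was 62.3%. Scaling had added 0.11 on the log2 scale to the fold changes of abundant genes in this comparison. It added less at low values, where the added 1 FPKM weighs more. The share was 48.0% without scaling and 48.9% with quantile normalization. Without the libraries labelled MCF7△ESR1 in the fit, 1384 genes were higher and 905 lower. Changes also ran along chromosomes: log2 fold changes of genes that lie 20 measured genes apart had a Spearman correlation of 0.142 across 13326 gene pairs, against at most 0.030 in 1000 shuffles of gene order.

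**Figure D2:**
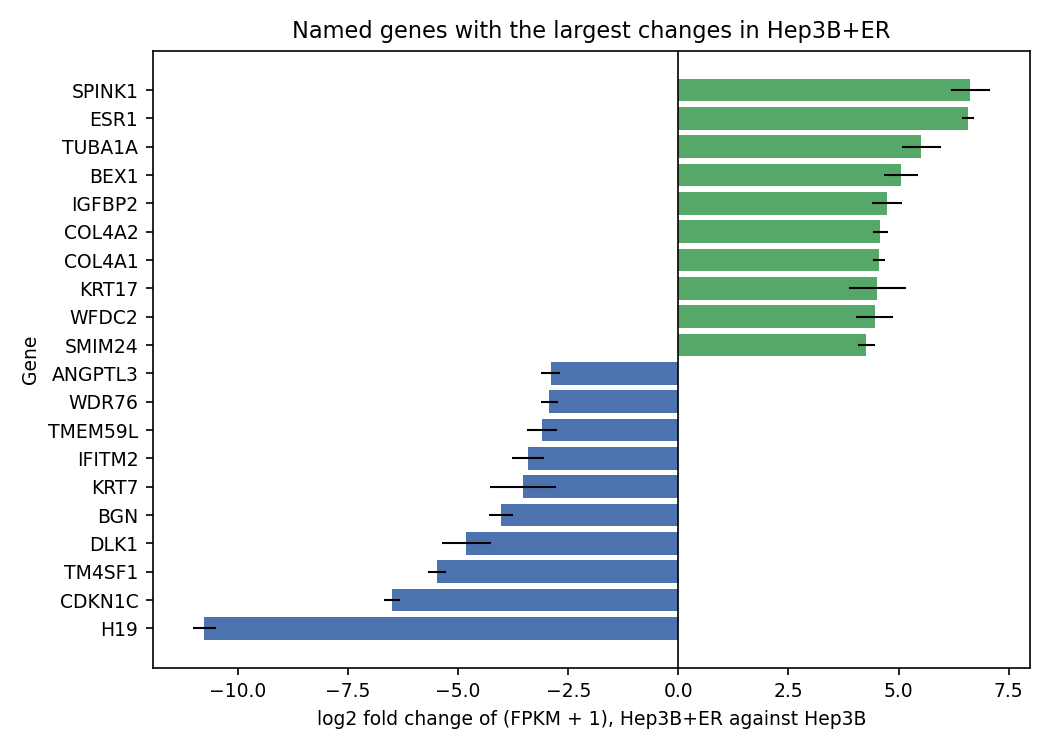
Log2 fold change of FPKM + 1 between Hep3B+ER and Hep3B (horizontal axis) for the 20 named genes with the largest changes (vertical axis). Bars start at 0 and lines show ± 1 SE from the limma fit with 2 libraries per group; values run from −10.76 for H19 to 6.63 for SPINK1.

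Of 54 estrogen-induced genes measured in Hep3B+ER, 8 were higher and 3 lower, the same counts adjusted over the list alone, with a median log2 fold change of 0.16. Camera, which sets a list against the other genes, gave an adjusted p = 0.435, and 0.205 to 0.884 over 17 alternatives, while fry, which tests a list against no change, gave an adjusted p = 0.0184 in the upward direction. The higher ones included TFF1, at 0.919 and 0.174 FPKM in Hep3B and 6.85 and 9.52 FPKM in Hep3B+ER (2.66 ± 0.50, adjusted p = 0.0134), the small heat shock gene HSPB8 (2.58 ± 0.40), FHL2 (2.17 ± 0.57) and NPY1R (1.56 ± 0.18). With the Hep3B+ER libraries counted as 1, 46 of 73 named genes of this comparison no longer passed, among them TFF1, HSPB8 and FHL2, while NPY1R did. Cholesterol biosynthesis genes had 5 of 25 higher and none lower (9 and none adjusted over the list alone), among them INSIG1 at 1.63 ± 0.34 and FDFT1 at 1.02 ± 0.21, which no longer passed with the libraries counted as 1. Camera gave an adjusted p = 0.000858 for this list, and adjusted p = 0.917 with an estimated correlation, and fry gave 0.191. Within Hep3B, 1 of these 25 genes was higher in replicate 1 than in replicate 2, and the median log2 ratio of replicate 1 to 2 was −0.84. Without replicate 1 the adjusted p was 0.110, and over the 17 camera alternatives it ran from 2.32e-10 to 0.917. Of 32 G2/M genes 2 were lower, PLK1 at −0.81 ± 0.22 and KIF23 at −0.70 ± 0.19, neither of which passed with the libraries counted as 1, and none were called adjusted over the list alone. Camera gave this list an adjusted p = 0.000128, and adjusted p = 0.917 with an estimated correlation, and fry gave 0.311. All 32 were higher in replicate 1 of Hep3B than in replicate 2, and without replicate 1 the adjusted p was 0.168, in a range of 2.32e-10 to 0.917 over the camera alternatives.

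Among p53 target genes 4 of 25 were higher and none lower, also adjusted over the list alone, with CDKN1A, a cell cycle inhibitor, at 2.62 and 7.48 FPKM in Hep3B and 50.2 and 54.1 FPKM in Hep3B+ER (3.36 ± 0.39, adjusted p = 0.00175). The list's median was −0.01 and its mean 0.27 (camera adjusted p = 0.692). TP53 itself, known to be deleted in Hep3B, was at a mean of 3.137 FPKM in Hep3B and 2.62 FPKM in Hep3B+ER. Basal epithelial markers had 3 of 12 higher and none lower (4 and none adjusted over the list alone), namely KRT17, LAMB3 and LAMC2 (camera adjusted p = 0.0874; 0.0433 with the Hep3B+ER libraries counted as 1, and 0.0210 to 0.535 over the camera alternatives; fry adjusted p = 0.0184). With the libraries counted as 1, LAMB3 no longer passed. Luminal markers had 4 of 25 higher and 1 lower (4 and 2 adjusted over the list alone; adjusted p = 0.690), with CLDN3 at 1.52 ± 0.24 and FOXA1 at −0.88 ± 0.19, neither of which passed with the libraries counted as 1. Of the hepatocyte secreted proteins 4 of 32 were lower and none higher, also adjusted over the list alone, AHSG, F2, FGG and ITIH2, with log2 fold changes of −1.62 to −1.11 (camera adjusted p = 0.0880; 0.00591 without replicate 2 of Hep3B, and up to 0.917 over the camera alternatives). None of these 4 passed with the Hep3B+ER libraries counted as 1 or without either of them. Wnt target genes had 1 of 15 higher and 2 lower (1 and 3 adjusted over the list alone; adjusted p = 0.0510). That list passed in 11 of its 17 camera alternatives, with an adjusted p from 0.00340 to 0.535, and with fry (adjusted p = 0.0184). Of type I interferon genes 4 of 34 were higher and 1 lower, also adjusted over the list alone (adjusted p = 0.540; 0.0138 with only the 4 libraries of the comparison). DTX3L, HERC5, OAS3 and IRF7 of these, and GDF15 and PHLDA3 of the p53 targets, no longer passed with the Hep3B+ER libraries counted as 1 or without either of them. IL32 was the 1 NF-kB gene of 20 that was higher (3.85 ± 0.20; list adjusted p = 0.690). In the remaining lists between 0 and 6 members were called in either direction over all genes and between 0 and 7 adjusted over the list alone, with camera adjusted p between 0.0831 and 0.960. Leaving out 1 library gave calls for 3 of them: hypoxia genes (adjusted p = 0.00417) and hepatocyte transcription factors (0.0455) without Hep3B replicate 2, and YAP and TEAD target genes (0.0223) without Hep3B replicate 1. With no filter, hepatocyte transcription factors and G1/S genes passed (both 0.0211), as did unfolded protein response genes (0.0179), which also passed with only the 4 libraries of the comparison (0.0262) and without the libraries labelled MCF7△ESR1 (0.0373). Fry called mesenchymal genes and fibroblast and endothelial markers (both 0.0184) and hepatocyte transcription factors (0.0444). The histone genes had a median of −0.07 and a mean of 0.08, and the fibroblast and endothelial markers a median of 0.27 with a downward camera direction.

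**Figure D3:**
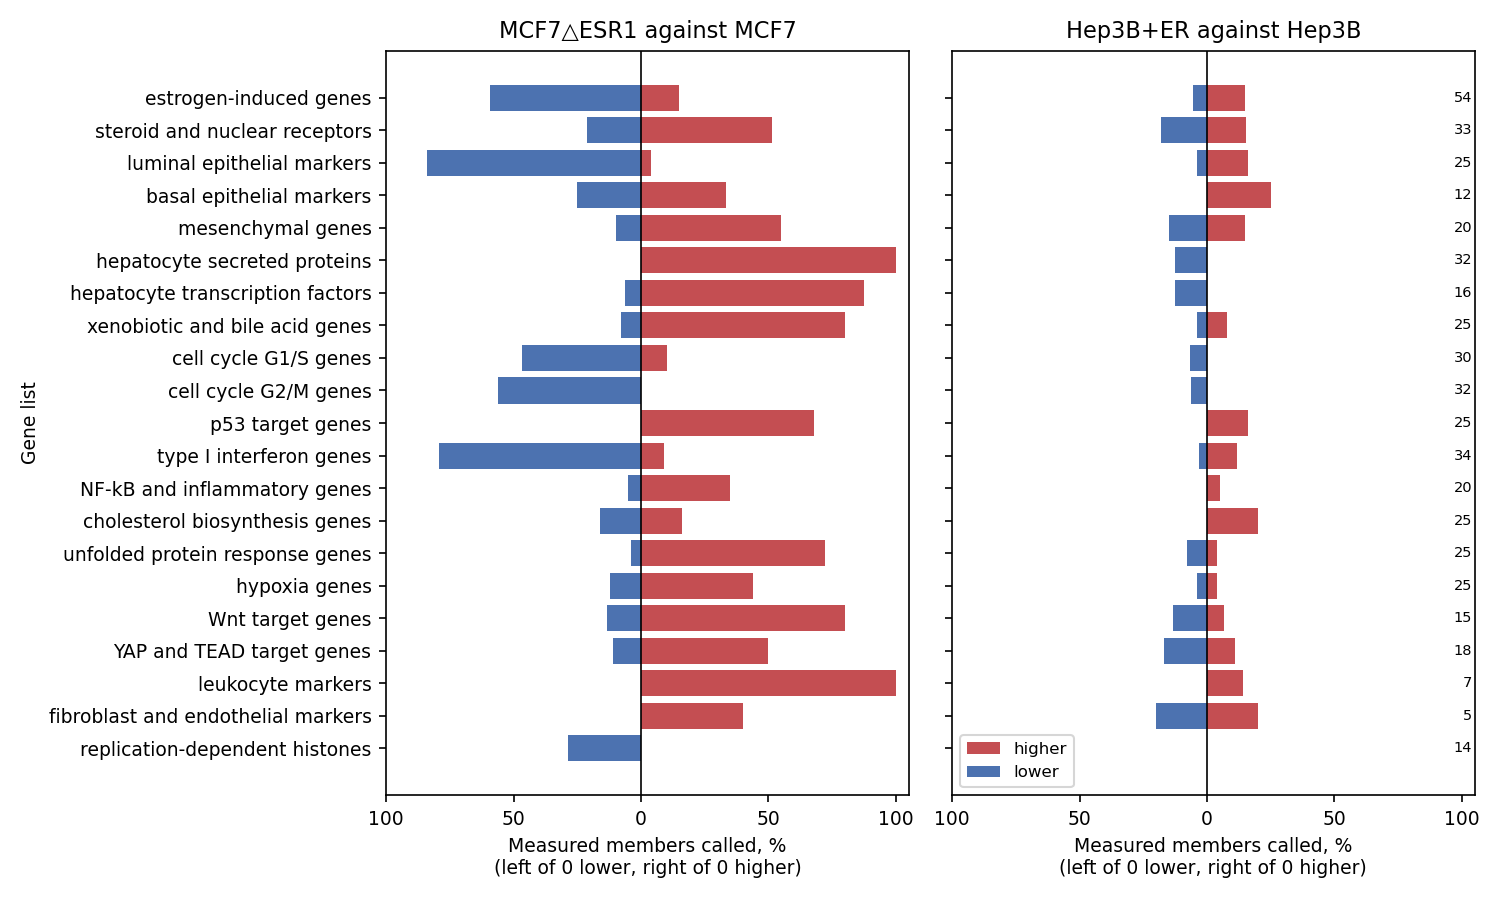
Share of the measured members of each of 21 gene lists (vertical axis) called higher (right of 0) or lower (left of 0), in percent, in the libraries labelled MCF7△ESR1 against MCF7 and in Hep3B+ER against Hep3B; the numbers at the right edge give the measured members. Hepatocyte secreted proteins reach 32 of 32 higher in the left panel, while 4 of the same 32 are lower in the right panel.

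Hep3B against MCF7, the comparison of the parental lines, set the scale for these differences. APOA2, an apolipoprotein, was at 9657 and 5812 FPKM in Hep3B and 11.7 and 14.4 FPKM in MCF7 (9.01 ± 0.25, adjusted p = 6.58e-07), and NTS, IGF2, ALDH1A1, AHSG, ALB, AGT, TF, CDKN2A and TM4SF4 were higher by 7.45 to 9.68. TFF1, IFI27, PREX1, SPDEF, CLDN7, BST2, SPINT2, CD9, IFITM1 and SULF2 had log2 fold changes of −10.39 to −6.72. In all, 4561 genes were higher and 4080 lower (4081 and 4682 with quantile normalization), 61.6% of the genes tested. With only the 4 libraries of this comparison 3967 were higher and 3469 lower. Hepatocyte secreted proteins had 27 of 32 higher and none lower, also adjusted over the list alone (camera adjusted p = 1.19e-09; adjusted p = 0.331 with an estimated correlation). Type I interferon genes had 30 of 34 lower and 1 higher (31 and 1 adjusted over the list alone; camera adjusted p = 6.86e-08, and adjusted p = 0.395 with an estimated correlation), the list in which the MCF7 libraries differed by a median of 1.72. NF-kB and inflammatory genes had 17 of 20 higher and 2 lower, also adjusted over the list alone, such as CXCL5 at 5.50 ± 0.27 (camera adjusted p = 0.000111; adjusted p = 0.331 with an estimated correlation). Estrogen-induced genes had 35 of 54 lower and 7 higher (38 and 7 adjusted over the list alone; camera adjusted p = 5.13e-06, and adjusted p = 0.0540 with an estimated correlation).

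Both ESR1 comparisons were then set side by side, each taken as the group with ESR1 against the group without it. They share no library, but each gene's spread came from 1 fit of all 8 libraries, so the calls of both pairs are not independent. Genes higher with ESR1 in both pairs numbered 539, against 402.7 from independent lists, and genes lower in both numbered 330, against 258.6. Opposite directions were rarer, with 181 against 243.2 and 318 against 428.2. Odds ratios were 1.642, 1.496, 0.658 and 0.639 in that order, and Fisher's exact test, two-sided across genes, which are not independent, gave adjusted p of at most 5.60e-07 for the 4 pairs. Across all genes the log2 fold changes correlated at Pearson r = 0.131 and Spearman rho = 0.105. With the Hep3B+ER libraries counted as 1, all 4 pairs of directions held far fewer genes. The Fisher tests above are of the fit that keeps both libraries. Genes higher with ESR1 in both pairs included TFF1, BASP1, GALNT3, HOXB7, PMEPA1, RNF223 and HLA-DRB1, the last of a family whose members can share reads. Genes that were lower in both with ESR1 included DLK1, TM4SF1, TIMP3, A2M, CRLF1, IGDCC3 and TMEM59L. IL32, BEX1, SMIM24, SPINK1, FST, FXYD2, EPDR1 and MPP1 were lower with ESR1 in the MCF7 pair and higher with ESR1 in the Hep3B pair. AHNAK, EFEMP1, H19, IRF7, KRT7, SEMA3C, TBX2 and WDR76 went the other way. The MCF7 side of each of these rests on the libraries labelled MCF7△ESR1, in which all 32 hepatocyte secreted protein genes were higher than in MCF7.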

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

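The difference between both ESR1 comparisons was tested for each gene, as the change from the group with ESR1 to the group without it in the MCF7 pair minus the same change in the Hep3B pair. It passed for 4125 genes on the higher side and 3246 on the lower side of 14024. The share on the higher side was 56.0%, and 45.4% with quantile normalization. Every one of these values rests on the libraries labelled MCF7△ESR1. Tests chosen after the result was seen are the one of a mixture of both lines, the 4-fold ratios of MTAP and TP53, those on the closeness of the Hep3B+ER libraries and that of the estrogen-induced list.

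On the higher side the log2 difference was 10.55 for SPINK1, 10.12 for LYZ, 9.70 for BEX1, 9.49 for CES1, 9.41 for IL32, 9.31 for SMIM24, 8.96 for APOA2, 8.90 for SERPINA1, 8.86 for ALB and 8.80 for SPP1. On the lower side it was −13.12 for H19, −10.04 for IFI27, −8.63 for SPTSSB, −7.51 for GATA3, −7.17 for CLDN7, −7.17 for SPINT2, −7.15 for SPDEF, −7.03 for TFF1, −7.00 for PREX1 and −6.95 for SEMA3C. TFF1 was lower without ESR1 in both pairs. Its log2 fold change was −9.69 in the MCF7 pair and 2.66 in Hep3B+ER against Hep3B, so the pairs differed in size and not in direction. Neither value separates ESR1 from other differences between the libraries compared.

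Gene lists differed as well by camera at the preset correlation, and each of these calls was lost with an estimated correlation, where the smallest adjusted p was 0.0681. For 10 of the 16 lists this was the only loss. The call held in 18 of 20 alternatives for G1/S and interferon genes and in 17 for unfolded protein response. It held in 14 for NF-kB, 13 for histone and 10 for hypoxia genes. For estrogen-induced genes, Wnt targets and hepatocyte transcription factors the estimated correlation lay below the preset, so a larger correlation did not end those calls. Without MCF7 replicate 2 the adjusted p was 0.18 for NF-kB, 0.117 for unfolded protein response, 0.127 for histone and 0.0786 for hypoxia genes, and with fry it was 0.108 for G1/S, 0.182 for interferon and 0.140 for histone genes. Median log2 differences above 0 were 6.95 for hepatocyte secreted proteins, 3.17 for xenobiotic and bile acid genes, 2.67 for hepatocyte transcription factors, 2.18 for leukocyte markers, 2.12 for Wnt targets, 2.02 for p53 targets, 1.63 for mesenchymal genes, 0.91 for the unfolded protein response, 0.88 for hypoxia genes and 0.44 for NF-kB genes. Those below 0 were −2.47 for luminal markers, −1.68 for interferon genes, −1.24 for estrogen-induced genes, −0.87 for G2/M genes, −0.85 for histone genes and −0.52 for G1/S genes.

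For the liver expression of the libraries labelled MCF7△ESR1, MCF7 cells that lost ESR1 are a poor account of it: MTAP and CDKN2A, which are known to be deleted in MCF7, were at 1.02 and 1.17 FPKM and at 0.345 and 0.557 FPKM in MCF7, and at 14.31 and 20.56 FPKM and at 7.76 and 14.6 FPKM in the libraries labelled MCF7△ESR1. The bound set beforehand was below 1 FPKM in MCF7, which MTAP narrowly missed and CDKN2A met, so a ratio of 4 was used in its place for MTAP and for TP53, which missed its bound in Hep3B too (3.53 and 2.75 FPKM). A mixture of Hep3B into MCF7 is argued against by hepatocyte secreted genes whose median lay 2.06 above Hep3B on the log2 scale, and by GATA3 at 0.000710 times its MCF7 mean, and Hep3B under a wrong label by TP53, deleted in Hep3B, at 9.004 times its Hep3B mean. MTAP and CDKN2A argue against MCF7 as the source of these libraries, with means 15.86 and 24.73 times as high as in MCF7. Of the accounts named here, another line than MCF7 is the one left. Which line was not tested, and the deletions are background knowledge. Any effect of ESR1 loss within these libraries cannot be told apart from a difference of line.

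For the closeness of the Hep3B+ER libraries, deeper sequencing alone would not bring abundant genes together, and over genes of at least 50 FPKM the SD of their log2 ratio was 0.068, against 0.408 to 0.463 in the other groups. For the larger number of genes listed above 0, depth remains a candidate explanation: 935 genes were above 0 in both Hep3B+ER libraries and at 0 in both Hep3B libraries, with a median of 0.0629 FPKM, against 73 the other way. Whether both Hep3B+ER libraries came from 1 culture or 1 RNA cannot be told apart from 2 very similar cultures, since the labels do not say, and the SD of 0.138 over genes of at least 1 FPKM goes with either.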

How the results depend on the processing

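Quantile normalization, the filter of 5 FPKM, counting the Hep3B+ER libraries as 1 and library weights were chosen after seeing the data. Of 122 alternative values of the gene counts, 9 moved by more than 1.5 times, all of Hep3B+ER against Hep3B, where 1371 genes were higher and 828 lower. Lower genes numbered 1269 with quantile normalization and 1288 with library weights, and higher genes 817 with the filter of 5 FPKM, which tests fewer genes. With the Hep3B+ER libraries counted as 1 the counts were 173 and 67; that fit has 1 library fewer and assumes that the lone one varies like the other groups, as do the fits that leave out a library. Leaving out 1 library of these groups gave 159 to 1156 higher and 69 to 750 lower genes, the lowest values without a Hep3B+ER library. Among genes called in both ESR1 comparisons, 539 were higher with ESR1 in both, 181 higher in the MCF7 pair and lower in the Hep3B pair, 318 the reverse and 330 lower in both. In that order counting the Hep3B+ER libraries as 1 gave 96, 10, 33 and 25, and leaving out 1 library gave 88 to 523, 10 to 195, 32 to 360 and 27 to 339. Quantile normalization gave 336 for the second and the filter of 5 FPKM 326 for the first. The cause of the shifts with quantile normalization and weights was not tested. No result changed direction with a call. Of 5318 alternative values of named genes 248 lost their call. Of 1533 of gene lists 95 lost and 47 gained one, and 49 of these losses came in the setting with an estimated correlation.

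The replicate number as a block gave 4254 higher and 3980 lower genes for MCF7△ESR1 against MCF7 and 1157 and 711 for Hep3B+ER against Hep3B, and no count moved by more than 1.5 times. Same-numbered libraries did not deviate together, with correlations of their deviations from −0.129 to 0.069 over the 6 pairs of groups, so the numbers were not taken as pairing. The planned count-based scalings and tests were not run, since they need counts, and depth, which is unknown, limits what can be said of low values.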

Other observations

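Beyond the comparisons above, the libraries labelled MCF7△ESR1 also differed from Hep3B, with 3533 genes higher and 3576 lower of 14024, a comparison chosen after seeing the data, as were the genes named here, the rule for rising and falling genes and the tests of the neighbours of rising genes and of the estrogen-induced list. The p53 target genes had 19 of 25 higher and none lower (20 and none adjusted over the list alone). Camera gave an adjusted p = 5.50e-07, and adjusted p = 0.472 with an estimated correlation. FDXR, a mitochondrial reductase, was at a mean of 87.7 FPKM against 3.50 FPKM in Hep3B. TP53 itself, known to be deleted in Hep3B, was at a mean of 28.25 FPKM against 3.137 FPKM in Hep3B. Wnt target genes had 11 of 15 higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.00193; adjusted p = 0.310 with an estimated correlation), among them SP5 at 83.9 and 98.3 FPKM against 2.51 and 1.37 FPKM. AKR1C1 and AKR1C3, close paralogs, were at 324 and 562 FPKM and at 144 and 124 FPKM, and below 1.5 FPKM in Hep3B. The neurotensin gene NTS went the other way, with a mean of 1.85 FPKM against 1972 FPKM in Hep3B.

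In Hep3B+ER, 70 genes rose from below 1 FPKM to at least 5 FPKM, ESR1 among them, and 18 fell from at least 5 FPKM to below 1 FPKM. The rising ones included HOXB7, HOXB9, IRF4, ACKR3, GJA4 and EYA4, at mean levels of 8.37, 9.61, 13.0, 17.1, 15.5 and 6.16 FPKM in Hep3B+ER and at most 0.0853 FPKM in Hep3B. Those that fell included H19, CDKN1C, TM4SF1, TIMP3 and COLEC12.

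For these genes and the way changes ran along chromosomes in Hep3B+ER against Hep3B, complete loss of chromosome segments is argued against as the source of the falls: 0.0% of the 18 genes had a nearest measured neighbour that fell below 1 FPKM as well, and of 25 neighbours with at least 5 FPKM in Hep3B none did. The same look at neighbours cannot decide whether gain of segments was a source of the rises. It does not separate added copies from other reasons for neighbours to rise together, and copies of a silent gene need not raise it. Of the 70 rising genes 4 (5.7%) had a neighbour that rose in the same way, against a mean of 0.692 in 10000 permutations (one-sided permutation p = 0.0466). Loss or gain of some copies of long segments stays open as a hypothesis, since genes 20 measured genes apart changed together (Spearman rho 0.142, against 0.015 between the 2 Hep3B libraries, 0.068 between the 2 MCF7 libraries and 0.118 for Hep3B against MCF7), and 14 of the 36 neighbours of the fallen genes were called lower and none higher; a bias with GC content was not tested because no genome sequence was used. Transcription driven by the added receptor cannot be told apart from differences between cultures for these genes, since every Hep3B+ER library carries both. The estrogen-induced list had a camera adjusted p = 0.435 and a fry adjusted p = 0.0184. That list is a separate set, with TFF1 also among the rising genes, so its tests cannot decide this for the rising and falling genes.

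Replicates within a group differed in whole gene lists. In Hep3B all 32 G2/M genes were higher in replicate 1 (median log2 ratio of replicate 1 to 2 of 0.46), while YAP and TEAD targets (−0.97), hypoxia genes (−0.84) and cholesterol biosynthesis genes (−0.84) were higher in replicate 2. In the libraries labelled MCF7△ESR1 29 of 32 hepatocyte secreted protein genes were higher in replicate 1 (median 0.90). In Hep3B+ER the same medians lay between −0.08 and 0.02 for the 21 lists.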
